A study of Rattus norvegicus with 6 samples.

How the data were processed

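Gene expression was measured by RNA sequencing in rat adipose-derived mesenchymal stem cells, stromal cells grown out of Sprague Dawley fat tissue. The cells were kept in medium free of branched chain amino acids (BCAA, that is leucine, isoleucine and valine) with serum. They were exposed for 12 h to vehicle or to 3.432 mM BCAA, in both cases together with 100 µM hydrogen peroxide, an oxidant. There were 6 libraries, 3 per group. RNA was isolated with TRIzol and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The BCAA composition and the vehicle are not given in the sources used here, and no condition without hydrogen peroxide was analysed here.

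The deposited table holds raw read counts per gene symbol for the 6 libraries, not normalized and not pooled. Trimmomatic, FastQC, STAR and HTSeq and the genome build rn6 are named in the submitters' processing notes. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be assigned with certainty, and reads of near-identical genes (the actin genes, Hspa1a and Hspa1b, the Ifit and Oas families) may be split or lost. The table has 21857 rows, each named by a gene symbol, and 5287 of them have no count in any library. It holds no row for unassigned reads. Library totals ran from 12725344 to 15739731 counts. No rn6 annotation was used here, so genes are given by symbol without coordinates, and transcript length and GC content were not tested.

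Column names were matched to the libraries' titles, and groups were taken from the titles. Counts of each pair of libraries were compared with a chi-square test over genes with at least 10 counts in the pair. The chi-square per degree of freedom was between 2.65 and 18.1 over the 15 pairs, so no library was a second copy of another. Replicate numbers are shared by the groups and were not taken as pairs, although library totals were close between equal numbers. Shared handling by number was thus not excluded, and the number as a block was among the alternatives. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical.

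The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, with robust estimation) on all 6 libraries with the group as the only term. TMM scaling was used, with filterByExpr at its defaults (minimum count 10, minimum total 15). The filter left 12298 genes, which held 99.9% of all counts. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. For a mean over several genes, the SE was the SD over those genes divided by the square root of their number. That SE treats genes as separate and does not measure the spread between libraries. CPM values use TMM-scaled library sizes.

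Before the data were examined, 35 gene lists were fixed from textbook knowledge, with 624 symbols. Of these, 609 were found in the table, 26 of them under an older or newer symbol from the RefSeq table of assembly GRCr8, and 545 were tested. The rest were not analysed here as list members. Among them was Mt-co3, which the deposited counts hold as Mt-cox3 (0.65% of counts on average) and which the symbol lookup missed. Lists with at least 3 tested genes (33 lists) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the 33 lists. Beside each list stands the number of members called over all genes and the number called when adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. No list call held with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and 7 of the 13 calls held with fry, which tests whether the genes of a list move, on balance, one way.

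The genes named were chosen by a rule fixed before the data were examined. They are Nat8l; the 10 called genes with the largest change in each direction with a mean of at least 1 CPM, a gene symbol and no overlap between groups; the 5 genes with the smallest p in each direction; and up to 4 members of each list with the smallest p. Genes named outside this rule are marked as chosen after their values were seen. Nat8l was put first from prior knowledge of the study, in which its level was recalled, without the paper at hand, as lower with BCAA, the reverse of the direction in these counts. That recollection was not checked.

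The fits were tested on counts simulated from the means, spreads and library sizes of these 12298 genes, with 200 genes changed. For the BCAA against vehicle comparison, edgeR recovered 18% of genes changed 1.25-fold, 58% at 1.5-fold, 76% at 2-fold and 98% at 3-fold. It also called 9 unchanged genes, and 0 genes in counts with no change. At 3-fold alone it recovered 49 genes, more than the 28 called in the real counts, so its adjusted threshold was easier to reach. No simulated library stood apart over many genes either. These rates may therefore be too high for the real comparison. With a list of interferon genes shifted 1.25-fold, camera with the preset correlation ranked it first with an adjusted p of 6.83e-08. With an estimated correlation the adjusted p of the same list was 0.657, and with fry 0.237. Each gene was drawn independently, so the simulated genes were not correlated. In the real counts the estimated correlation was 0.145 for the smooth muscle list and 0.175 for the ATF4 list. It was -0.0295 for the interferon list and -0.0498 for the p53 list. The simulation therefore cannot tell which correlation setting suits the real lists. It does show that the estimated setting can miss a list that is shifted. For the real interferon list the unadjusted camera p rose from 1.6e-07 to 0.0048 with the estimate, although that lay below the preset 0.01. Failing to pass with the estimated setting is therefore weak evidence against a list.

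Alternatives were RLE, upper-quartile and no scaling factors; no filter and a filter of 1 CPM in 3 libraries; DESeq2 1.42.0; limma-voom; the replicate number as a block; each library left out in turn; and stricter thresholds. A fit without the mitochondrially encoded genes was added after seeing the data. With no label naming a batch, none was fitted.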

Results

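Rat adipose-derived mesenchymal stem cells were profiled by RNA sequencing after 12 h with vehicle (3 libraries) or 3.432 mM BCAA (3 libraries), all in 100 µM hydrogen peroxide. The comparison asks which transcripts differ between cells given BCAA and cells left in BCAA-free medium with serum, both under hydrogen peroxide. It cannot tell an excess of BCAA from an end to their shortage. Library totals were 14484051, 15739731 and 12725344 counts in vehicle replicates 1 to 3 and 14482260, 15654060 and 12802663 in BCAA replicates 1 to 3. Equal replicate numbers thus had similar totals, although the labels name no shared batch. Pearson correlations of log2 CPM across genes were 0.988 to 0.993 for the 6 pairs within a group and 0.986 to 0.992 for the 9 pairs between groups. The first principal component held 29.1% of the variance and set vehicle replicate 1 (score 26.8) apart from the other 5 libraries, which lay between -15.2 and 0.54. On the second (23.6%), vehicle replicates 2 and 3 lay at -15.6 and -16.2, vehicle replicate 1 at 4.88 and the BCAA libraries between 3.58 and 13.97. Mitochondrially encoded genes took 6.58% of the counts of vehicle replicate 1 and 4.92% and 4.91% of those of the other vehicle libraries. Their share was 5.47% ± 0.962 (SD, n = 3) with vehicle and 5.87% ± 0.330 (SD, n = 3) with BCAA (two-sided exact permutation test, p = 0.6; the smallest p this design allows is 0.1).

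**Figure D1:**
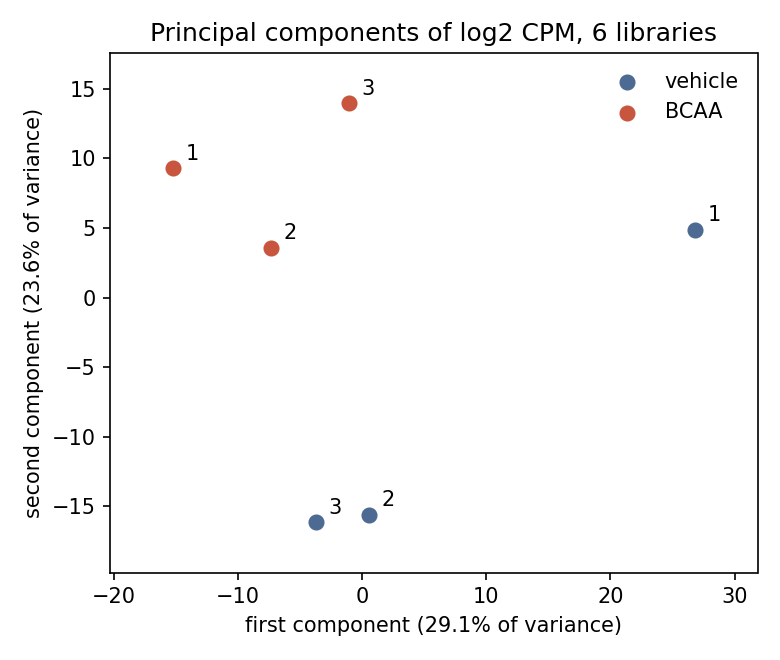
Scores of the 6 libraries on the first (x axis, 29.1% of the variance) and second (y axis, 23.6%) principal components of log2 CPM; points are libraries, numbered by replicate. Vehicle replicate 1 lies at 26.8 on the first component, away from the other 5 libraries.

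Nat8l, which encodes the enzyme that makes N-acetylaspartate from aspartate and acetyl-CoA, was at 75.6 ± 4.64 CPM with BCAA and 55.6 ± 8.71 CPM with vehicle (SD, n = 3 each). The log2 fold change was 0.44 (SE 0.10), a 1.36-fold higher level in the BCAA group. All 3 BCAA libraries (70.9 to 80.2 CPM) lay above all 3 vehicle libraries (45.8 to 62.3 CPM), which chance gives for 10% of genes in one direction or the other. The unadjusted p was 0.00077 and edgeR's adjusted p was 0.094, so the gene did not pass the threshold. With DESeq2, without the low-count filter and without vehicle replicate 1, where the log2 fold change was 0.33, the adjusted p was 0.016, 0.015 and 0.014. Over all alternatives it ran from 0.014 to 0.38, the highest without BCAA replicate 2. The direction of this and every other difference rests on the names of the table's columns, which match the titles of the libraries. No other measurement was used to check them, and all directions would turn if the group names were exchanged. Of the other genes of N-acetylaspartate metabolism only Aspa, the hydrolase that splits it, was tested, and its level was under 1 CPM in both groups.

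Of 12298 genes tested, 28 passed an adjusted p of 0.05 (edgeR, Benjamini-Hochberg), 7 higher and 21 lower with BCAA. In all 28 the libraries of the groups did not overlap, which the call itself makes likely and which adds no support to it. At least a 1.5-fold change was seen in 12 of them. The typical SE of a log2 fold change was 0.11. At an unadjusted p under 0.05 there were 1450 genes, against 615 expected by chance, and this number was 956 without BCAA replicate 1 and 2274 without vehicle replicate 1. With DESeq2 the count was 127 (55 higher, 72 lower) and without the low-count filter 124 (57 higher, 67 lower), so neither the count nor the excess of lower genes was stable. The count was 500 without vehicle replicate 1 (229 higher, 271 lower), with all 28 genes among them, and between 7 and 11 without any one of the other 5. Without scaling factors 11 genes were higher and 18 lower. With the replicate number as a block 6 genes were called.

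Acta2, smooth muscle actin, fell 1.82-fold, from 36.0 ± 0.884 to 19.8 ± 0.707 CPM (log2 fold change -0.86, SE 0.09, adjusted p = 0.00059). Ctgf (Ccn2), a matricellular growth factor, fell 1.65-fold from 728 ± 26.2 to 442 ± 23.2 CPM (adjusted p = 0.00014). Tagln, which encodes the actin-binding protein transgelin, fell 1.53-fold from 794 ± 32.7 to 519 ± 13.7 CPM (adjusted p = 0.00036). Star, the carrier of cholesterol into mitochondria, fell 1.52-fold from 348 ± 14.1 to 229 ± 11.3 CPM, and Ptx3, a secreted pattern recognition protein, fell 1.48-fold from 408 ± 18.2 to 276 ± 7.44 CPM. Tslp, an epithelial and stromal cytokine, fell 1.63-fold, and Cdo1, the cysteine dioxygenase, fell 1.59-fold. Vgll3, a cofactor of TEAD transcription factors, fell 1.55-fold, the vasopressin receptor Avpr1a 1.53-fold, and the tropomyosin gene Tpm2 1.42-fold. Ctgf, Tagln, Acta2, Star and Ptx3 stayed past the threshold with each library left out in turn, as did Rsad2 and Atf3, and the other 21 called genes lost the call without at least 1 library. The unnamed gene model AABR07052519.1, chosen after its values were seen, was the only called gene with a change of over 2-fold, with 14 to 22 counts per vehicle library and 1 to 3 per BCAA library.

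All 7 genes that rose are named here. Rsad2, which encodes the antiviral protein viperin, rose 1.83-fold from 50.9 ± 3.27 to 93.2 ± 2.77 CPM (log2 fold change 0.87, SE 0.08, adjusted p = 0.00014). Atf3, a stress-induced transcription factor, rose 1.65-fold from 46.2 ± 3.25 to 76.1 ± 6.05 CPM (adjusted p = 0.0015). The interferon-induced genes Ifit3 and Oasl rose 1.62-fold and 1.49-fold (adjusted p = 0.017 for each). Hpx, the haem-binding plasma protein hemopexin, rose 1.44-fold, Ndrg1, a gene induced by hypoxia and stress, 1.32-fold, and Enc1, an actin-associated protein, 1.31-fold.

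**Figure D2:**
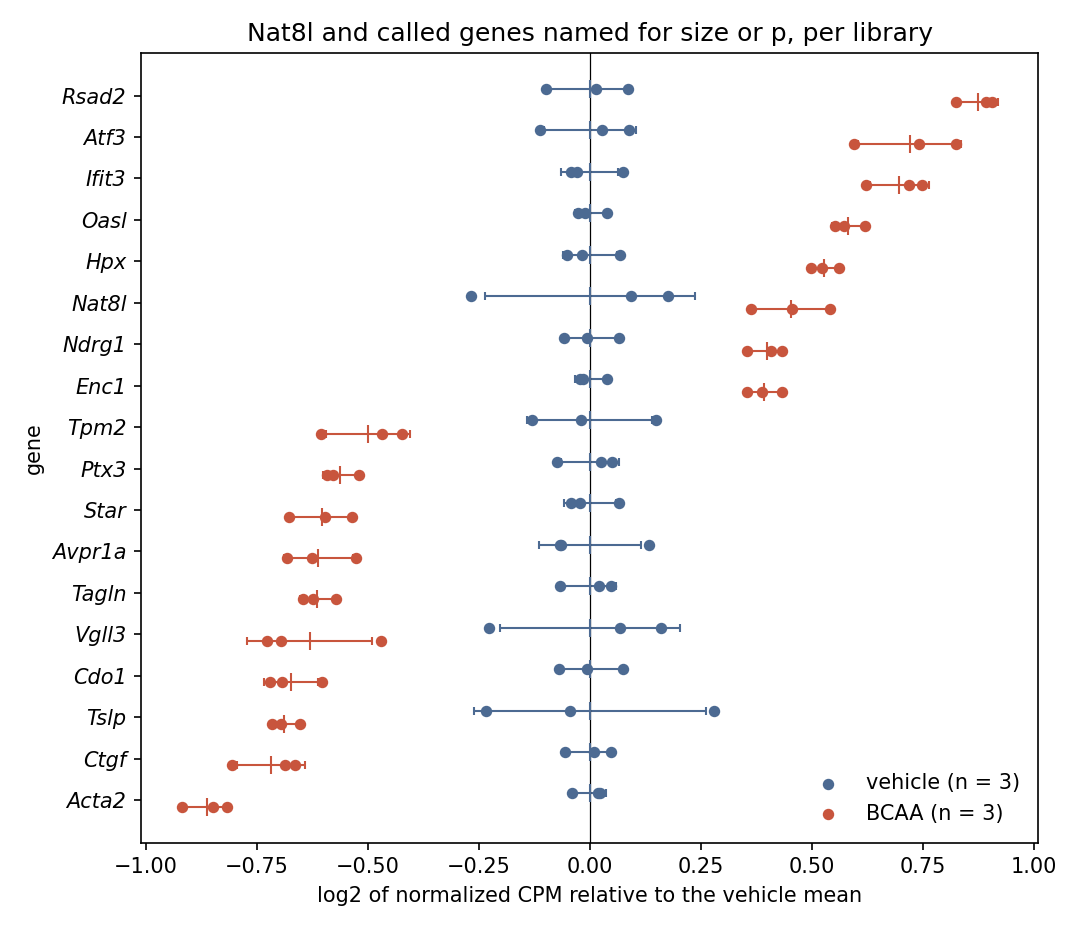
Log2 of normalized CPM relative to the mean of the vehicle libraries (x axis) for Nat8l and the 17 called genes named for the size of their change or their p (y axis); points are libraries, ticks are group means and bars are SD (n = 3). The groups do not overlap for any of these genes, which the naming rule required of those named for size. Nat8l, whose adjusted p was 0.094, has the vehicle library at 45.8 CPM well below the other vehicle libraries.

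Of the 33 gene lists tested, 13 passed an adjusted p of 0.05 with camera, 8 higher and 5 lower with BCAA. With an estimated correlation between genes none of the 33 passed, but that setting also missed the shifted list in the simulation. The adjusted p with an estimated correlation is given beside each of the 13 below. Within most of these lists few members passed the threshold alone. Member counts given below without vehicle replicate 1 come from the fit that called 500 genes. Leaving out any other library called only 7 to 11 genes, so those member counts add no support to a list.

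Genes that mark smooth muscle cells and pericytes, most of them parts of the contractile apparatus, lay lower with BCAA as a group (median log2 fold change -0.36; camera adjusted p = 2.0e-06; adjusted p = 0.17 with an estimated correlation). Of 8 members tested, Acta2 and Tagln fell and 6 did not pass, and 5 were lower when adjusted over the list alone. Cnn1, calponin, was at 17.8 ± 0.275 CPM with BCAA and 25.0 ± 0.979 CPM with vehicle (adjusted p = 0.057). The smooth muscle myosin Myh11, chosen after its values were seen, had a log2 fold change of -0.23 (SE 0.09). Without vehicle replicate 1, 3 members were called lower.

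Genes for paracrine growth and angiogenic factors also lay lower (median -0.18; camera adjusted p = 0.00028; adjusted p = 0.17 with an estimated correlation). Of 25 tested, Ctgf and Cyr61 fell and 23 did not pass. Adjusted over the list alone, 11 were lower and 1 higher. Cyr61 (Ccn1), a matricellular protein, fell 1.37-fold from 402 ± 16.6 to 293 ± 9.82 CPM (adjusted p = 0.0059). Thbs1, thrombospondin 1, was at 3075 ± 264 CPM with vehicle and 2399 ± 144 CPM with BCAA (adjusted p = 0.062). Cxcl12, a chemokine that attracts progenitor cells, was at 697 ± 37.8 and 569 ± 6.91 CPM (adjusted p = 0.066). Ctgf, Cyr61 and Thbs1 are matrix-associated proteins as well as growth or angiogenesis regulators. Without vehicle replicate 1, 9 members were called lower and 1 higher.

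Interferon response genes lay higher with BCAA (median 0.25; camera adjusted p = 2.7e-06; adjusted p = 0.16 with an estimated correlation). Of 17 tested, Rsad2, Ifit3 and Oasl rose and 14 did not pass. Adjusted over the list alone, 5 were higher and 0 lower. Isg15, a ubiquitin-like modifier, was at 10.5 ± 0.722 CPM with BCAA and 6.28 ± 1.10 CPM with vehicle (adjusted p = 0.071). NF-kB inflammatory genes did not pass, with 5 higher and 15 lower in sign (median -0.09; camera adjusted p = 0.17), and without vehicle replicate 1 their median was -0.03 (camera adjusted p = 0.66). Of 20 tested no gene was called, and 2 were higher and 1 lower when adjusted over the list alone, namely Cxcl10, Ccl5 and Icam1. The interferon-inducible chemokines Cxcl10 and Ccl5 had log2 fold changes of 0.60 (SE 0.13) and 0.68 (SE 0.17), while Icam1 and Cxcl1 had -0.21 (SE 0.06) and -0.23 (SE 0.08). Markers of macrophages and leukocytes lay at a median of -0.03 (11 tested, none called). Without vehicle replicate 1, 4 interferon genes were called higher.

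The ATF4, p53 and heat shock lists lay higher, while the endoplasmic reticulum chaperones (17 tested, median -0.07, camera adjusted p = 0.13) and the NRF2 and antioxidant genes (18 tested, median 0.03, camera adjusted p = 0.29) did not pass. In the ATF4 amino acid response (median 0.09; camera adjusted p = 2.0e-05; adjusted p = 0.26 with an estimated correlation), Atf3 rose and 26 of 27 did not pass, while 8 were higher when adjusted over the list alone. The lipoprotein receptor gene Vldlr had a log2 fold change of 0.35 (SE 0.07), the secreted glycoprotein gene Stc2 0.51 (SE 0.13) and the pseudokinase gene Trib3 0.29 (SE 0.08), with adjusted p from 0.057 to 0.15. Of 19 p53 targets none was called (median 0.17; camera adjusted p = 0.0060; adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, 3 were higher, namely Tp53inp1 (log2 fold change 0.56, SE 0.14), the cell cycle inhibitor Cdkn1a (0.21, SE 0.06) and Mdm2, the ligase that degrades p53 (0.24, SE 0.07). Of 12 heat shock genes none was called (median 0.12; camera adjusted p = 0.014; adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 4 were higher, among them Hspa1b (0.36, SE 0.08) and Hsph1 (0.24, SE 0.06), and 1 was lower, the mitochondrial chaperonin gene Hspe1 (-0.46, SE 0.09). The call of the heat shock list was lost without vehicle replicate 2 or 3 or BCAA replicate 2 or 3, with adjusted p from 0.062 to 0.079. Leaving out vehicle replicate 1 gave 4 ATF4, 2 p53 and 5 heat shock genes called higher and 1 heat shock gene called lower.

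Mitotic genes lay higher (19 tested, none called; median 0.26; camera adjusted p = 5.9e-06; adjusted p = 0.17 with an estimated correlation). Leaving out vehicle replicate 1 gave 2 of them called higher and a median of 0.33. The proliferation marker Mki67 was at 14.6 ± 0.806 CPM with BCAA and 9.58 ± 2.28 CPM with vehicle, with an adjusted p of 0.13 over all genes and 0.032 when adjusted over the list alone, where it was the only one of the list. DNA replication genes lay higher too (20 tested, none called; median 0.11; camera adjusted p = 0.034; adjusted p = 0.26 with an estimated correlation), with 1 higher when adjusted over the list alone, Cdc45 (log2 fold change 0.83, SE 0.22). This call was lost without vehicle replicate 2 or 3 or BCAA replicate 2, with adjusted p from 0.063 to 0.13.

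Genes for nuclear-encoded subunits of oxidative phosphorylation lay slightly lower (26 tested, none called over all genes or adjusted over the list alone; median -0.11; camera adjusted p = 0.00069; adjusted p = 0.26 with an estimated correlation). Ndufb8, a complex I subunit, had a log2 fold change of -0.20 (SE 0.07). Mitochondrially encoded genes had a median of -0.04 (12 tested, Mt-cox3 not among them, none called; camera adjusted p = 0.92). Without vehicle replicate 1 their median was 0.18 and the list passed upward at the preset correlation (camera adjusted p = 0.017) but not with an estimated correlation (adjusted p = 0.55). Extracellular matrix genes (22 tested, median -0.09, camera adjusted p = 0.017) and ribosome biogenesis genes (20 tested, median -0.10, camera adjusted p = 0.023) lay lower, with no member called over all genes or adjusted over the list alone. For both the adjusted p was 0.26 with an estimated correlation. The matrix protein Sparc had a log2 fold change of -0.18 (SE 0.06). The matrix list lost its call without vehicle replicate 2 or 3 (adjusted p = 0.065 and 0.083), and the ribosome biogenesis list without vehicle replicate 1 (median -0.03, adjusted p = 0.34) or BCAA replicate 2 (adjusted p = 0.062). Leaving out vehicle replicate 1 gave 2 ribosome biogenesis, 2 matrix and 1 oxidative phosphorylation gene called lower and 1 matrix gene called higher.

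Of the other lists that passed upward, hypoxia and glycolysis (20 tested, median 0.07, camera adjusted p = 0.034; adjusted p = 0.42 with an estimated correlation) held Ndrg1 as its only called gene, and 5 were higher when adjusted over the list alone, with Hk2, a hexokinase, at a log2 fold change of 0.28 (SE 0.08). Cholesterol synthesis genes (20 tested, none called over all genes or adjusted over the list alone, median 0.09) had a camera adjusted p of 0.046 and an adjusted p of 0.26 with an estimated correlation. Insig1, the sterol sensor partner, had a log2 fold change of 0.19 (SE 0.06). The hypoxia call was lost without vehicle replicate 1 or 3 or BCAA replicate 2 or 3 (adjusted p from 0.075 to 0.20), and the cholesterol call without any library but BCAA replicate 1 (adjusted p from 0.065 to 0.26) and without the low-count filter (adjusted p = 0.051). Leaving out vehicle replicate 1 gave 4 hypoxia and 2 cholesterol genes called higher.

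**Figure D3:**
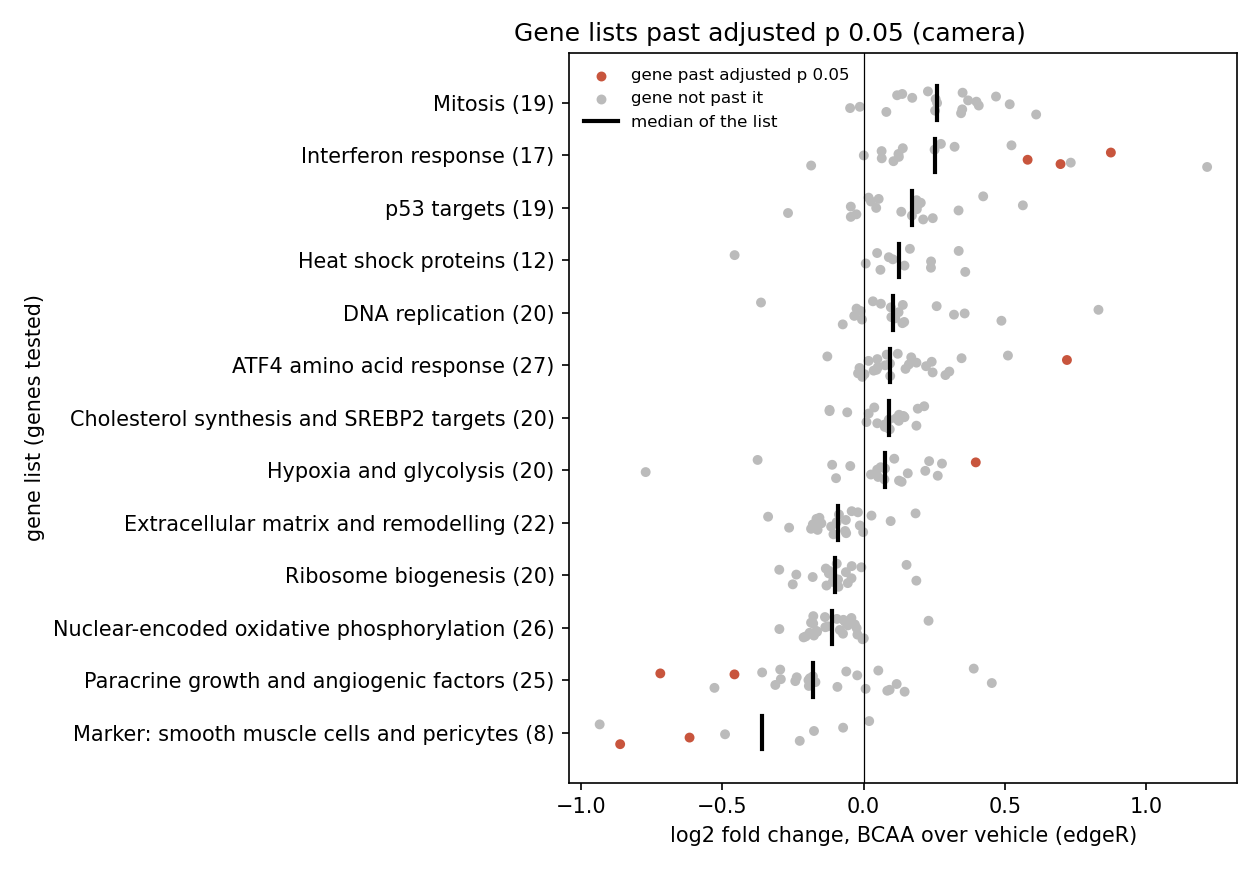
Log2 fold change of BCAA over vehicle from edgeR (x axis) for each tested member of the 13 gene lists that passed an adjusted p of 0.05 with camera at the preset correlation (y axis, number of genes tested in brackets). Points are genes, coloured where the gene passed an adjusted p of 0.05, and bars are list medians, which run from -0.36 for smooth muscle and pericyte markers to 0.26 for mitotic genes.

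The other 20 lists did not pass. Of the genes of BCAA breakdown and its regulators, 24 were tested and none was called over all genes or adjusted over the list alone (median -0.03; camera adjusted p = 0.38). The smallest p was that of Auh, an enzyme of leucine breakdown (log2 fold change -0.20, SE 0.08), followed by Bckdha, a subunit of the branched chain ketoacid dehydrogenase (-0.19, SE 0.08). Enzymes and readers of histone H3 lysine 9 methylation gave none of 18 over all genes or adjusted over the list alone (median 0.03; camera adjusted p = 0.40), with Kdm3a, a lysine 9 demethylase, at 0.20 (SE 0.08). Of 20 apoptosis regulators none was called over all genes and 2 were higher when adjusted over the list alone, namely Bid (0.31, SE 0.08) and Apaf1 (0.29, SE 0.08), and the list had a camera adjusted p of 0.40. Among NRF2 and antioxidant genes, Hmox1, haem oxygenase 1, was the only one of 18 to pass adjusted over the list alone (0.27, SE 0.07; adjusted p = 0.13 over all genes; camera adjusted p = 0.29 for the list). In fatty acid synthesis and storage, Plin2 (0.28, SE 0.06) and Scd (0.26, SE 0.06) were 2 of 12 to pass adjusted over the list alone (camera adjusted p = 0.17 for the list). Osteogenic and chondrogenic genes had 2 of 8 higher when adjusted over the list alone, Spp1 (0.26, SE 0.07) and Runx2 (0.36, SE 0.10), with a camera adjusted p of 0.37. Stromal identity genes had 1 of 13 lower when adjusted over the list alone, Mcam (-0.33, SE 0.08), with a camera adjusted p of 0.52. Immediate early genes had 3 higher and 1 lower of 18 when adjusted over the list alone, with Dusp1 at 0.27 (SE 0.06) and Nr4a3 at -0.48 (SE 0.11), and a camera adjusted p of 0.52. Genes of the 2-oxoglutarate and TCA cycle (27 tested), cytosolic tRNA synthetases (17), peroxisome (18), lysosome and TFEB targets (22), endoplasmic reticulum chaperones (17) and adipocyte differentiation (8) had no member called over all genes or adjusted over the list alone, with camera adjusted p from 0.13 to 0.92. The same held for markers of endothelial (3 tested), Schwann (3) and skeletal muscle cells (3), with camera adjusted p from 0.58 to 0.99. Mesothelial and epithelial markers had 2 tested genes, too few for a list test. The median, the mean and the camera direction differed in sign for the TCA cycle, lysosome, peroxisome and Schwann lists.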

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

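The 17 called genes named for the size of their change or their p kept their direction in all 255 values recomputed under the alternatives, and 194 of these passed. RLE factors, upper-quartile factors, limma-voom, a filter of 1 CPM in 3 libraries and, added after seeing the data, leaving out mitochondrially encoded genes moved the count of called genes to between 27 and 33, against 28. Without scaling factors 11 genes were higher. Without a low-count filter 124 genes were called (57 higher, 67 lower) with Nat8l at a log2 fold change of 0.45, and DESeq2 called 127 (55 higher, 72 lower), with Nat8l at 0.44. Nat8l passed in both, and they held 28 and 27 of the 28 genes; the cause was not tested. With the replicate block 6 genes were called (1 higher, 5 lower), all of them among these 17. Deviations of equally numbered libraries from their group means correlated at -0.07, 0.11 and -0.15, and not every library correlated best with its own number. Library totals were nonetheless close between equal numbers, so shared handling by number was not excluded. An adjusted p under 0.01 left 9 genes (2 higher, 7 lower), and a 1.5-fold minimum left 12 (3 higher, 9 lower). Leaving out each library in turn gave 7 to 500 genes (2 to 229 higher, 5 to 271 lower), 7 to 17 of the 17 named genes and a Nat8l log2 fold change of 0.33 to 0.53. The 500 came without vehicle replicate 1, where the common coefficient of variation between replicates fell to 0.0617 from 0.0850; the 472 genes gained had the same direction with that library. Camera called 13 lists; with an estimated correlation 0 passed (smallest adjusted p 0.16), fry called 7, the block 10 and leave-one-out fits 8 to 13. Adjusted p for the mitochondrially encoded list ran from 0.017, upward, to 0.98 over the leave-one-out fits, with its direction turned without vehicle replicate 1 and BCAA replicates 1 and 2. Smtn turned direction without vehicle replicate 3 and BCAA replicate 1, over a range of -0.0437 to 0.0494. The first component held 28.7% of the variance with a prior count of 0.5 and 28.1% over the 500 most variable genes, against 29.1%. At this depth and spread the smallest simulated change was recovered in 18% of genes, a rate that may be too high for the real counts. The absence of a call therefore says little about small changes.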

Other observations

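The 4 gene lists added here (YAP/TAZ, SRF/MRTF, TGF-beta/SMAD and MHC class I) were chosen after the called genes had been seen, and the YAP/TAZ, SRF/MRTF, smooth muscle and leukocyte tests, and the test of vehicle replicate 1 on the smooth muscle and paracrine lists, after values of their members had been seen, so the p-values of the YAP/TAZ and SRF/MRTF lists describe these genes and are no independent evidence.

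Of 28 tested targets of the transcription factor SRF and its cofactor MRTF, Tagln, Acta2, Myl9, Csrp1 and Tpm2 fell, 23 did not pass, and 24 had a negative fold change (median -0.27; camera adjusted p = 7.6e-12 over 4 added lists; adjusted p = 0.0054 with an estimated correlation). Adjusted over the list alone, 15 were lower and 1 was higher, while 9 lay within 0.1 of 0, so the list does not stand for the actin cytoskeleton as a whole. Members short of the threshold included the actinin gene Actn1 (log2 fold change -0.32, SE 0.06) and Actb (-0.29, SE 0.06), an actin gene at high abundance that is often used as a reference, and in the other direction the integrin gene Itga5 (0.28, SE 0.06). Of 20 tested targets of the cofactors YAP and TAZ, Ctgf, Cyr61 and Amotl2 fell and 17 did not pass (median -0.16; camera adjusted p = 3.7e-05; adjusted p = 0.030 with an estimated correlation), with 5 lower when adjusted over the list alone. Igfbp3, a binding protein of insulin-like growth factors, had a log2 fold change of -0.31 (SE 0.06). Other called genes outside the naming rule, chosen after their values were seen, were Pak1, a kinase of the cytoskeleton (-0.47, SE 0.07), the kinase Nuak1 (-0.45, SE 0.08), the matrix proteoglycan Prelp (-0.35, SE 0.06), Uap1, an enzyme of hexosamine synthesis (-0.34, SE 0.06), Pmp22 (-0.48, SE 0.08) and the unnamed gene model LOC100365810 (-0.43, SE 0.07).

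The lower smooth muscle marker and paracrine lists, in which 2 of 8 and 2 of 25 tested genes were called, were weighed against a single unusual library. Without vehicle replicate 1 these lists, fixed before the data were examined, had medians of -0.34 and -0.14 against -0.36 and -0.18 with it, and both still passed at the preset correlation (camera adjusted p = 9.0e-05 and 0.0039; adjusted p = 0.26 for each with an estimated correlation), which argues against that library alone as the source. Fewer smooth muscle cells or pericytes in the BCAA cultures remains open: the 5 other tested markers had a mean of -0.28 (SE 0.17), against -0.65 for Acta2, Tagln and Cnn1, with Smtn at 0.02 (SE 0.09). Without Actg2 (-0.93, SE 0.35, at 1.46 CPM) the other 4 had a mean of -0.11 (SE 0.05). Acta2, Tagln and Cnn1 were set apart, and Actg2 left out, after values had been seen, so this gap cannot decide the question. Whether stromal cells also make these 4 transcripts was not measured. The 15 tested TGF-beta/SMAD targets had a median of -0.04, with 9 lower and 6 higher in sign and Ctgf the only one called (camera adjusted p = 0.105; adjusted p = 0.27 with an estimated correlation; unadjusted p of 0.017 without vehicle replicate 1). The SRF/MRTF and YAP/TAZ target lists lay lower, as given above. Whether lower activity of SRF/MRTF, YAP/TAZ or TGF-beta/SMAD lay behind the pattern was not decided. For the members not called of these 3 target lists, in that order, the unadjusted camera p was 3.74e-07, 0.00821 and 0.326. The first 2 lists had been seen low and the last lost its called gene, so these values neither support nor exclude lower activity. Cell density and transcript length, which were not tested, also stay open.

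The higher interferon response genes were weighed against leukocytes carried in the cultures. The 11 tested leukocyte markers had a mean log2 fold change of -0.0023 (SE over markers 0.033), below the interferon median of 0.25. Of these markers 5 were higher and 6 lower in sign, from Cd74 at 0.17 (SE 0.11) to Lyz2 at -0.20 (SE 0.08). The most abundant, Lyz2 and Cd14 (-0.12, SE 0.07), were both lower. Ptprc (0.10, SE 0.12), Csf1r (0.09, SE 0.11), Cd68 (0.08, SE 0.10) and Adgre1 (0.05, SE 0.11) were higher, each by less than its SE. Without vehicle replicate 1 the marker median was 0.06, against 0.32 for the interferon list. These values argue against more leukocytes as the only source of the pattern, but a change within such cells remains open. No single library carried the higher interferon genes, since their lowest median over the 6 leave-one-out fits was 0.19 and the highest 0.35. A wider interferon response was tested with 10 genes of MHC class I presentation, which had a mean of 0.01 (SE 0.04), with Tap1 at 0.22 (SE 0.09); the unadjusted camera p was 0.667. Since 5 were higher and 5 lower in sign and a wider response need not move them as far, this leaves it open.

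Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 28 genes, and the highest other gave 0. Only 1, again the real one, gave as many as 13 lists, and the others gave 3, 0, 1, 1, 0, 0, 1, 2 and 1. Most of those splits thus called a list at the preset correlation although each side mixed BCAA and vehicle libraries. No such split could balance the groups, so part of any BCAA difference stayed between the sides. Their list calls are therefore not calls made without a difference. Mixing can also widen the spread within a side, so the gene counts of 0 in these splits are a weak comparison. With 10 splits a share under 0.05 cannot be reached.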
